A study of Homo sapiens with 4 samples.

How the data were processed

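Ribosome footprints were sequenced from Hermes 4B, an immortalised line of human skin melanocytes, the pigment-producing cells of the skin. Cells had been transfected with a control siRNA or with an siRNA against CDH3-AS1, a noncoding RNA transcribed antisense to CDH3, the gene of P-cadherin. Per the labels' protocols, siRNAs were used at 25 to 50 nM, ribosomes were held on the RNA with 100 µg/mL cycloheximide, and RNase I digestion left the fragments that ribosomes protect. Each siRNA had 2 libraries, 1 in batch 1 and 1 in batch 2. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these 4 samples, which may be technical. With 2 libraries against 2, an exact permutation test of a single gene cannot give a two-sided p below 0.333.

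Per the file headers, the deposited tables list for each transcript the count of reads in its 5′ UTR, coding sequence and 3′ UTR and in all 3 together. The authors also deposited RPKM values for each region, and the other columns give the lengths of the regions in bases. Checked on the values, the RPKM were scaled by the library's total over all regions. The submitters' processing notes name the build hg38 and DESeq2. The aligner, the counting tool, the annotation release, the read filters and the use of strand are not given in the sources used here. No RNA-seq was analysed here, so the values are ribosome density and not translational efficiency. Reads that fit several transcripts, or near-identical genes such as actins and ribosomal proteins, can have been split or counted more than once, and those genes are uncertain. Tables held 38455 transcripts of 14355 gene names, of which 13900 matched an NCBI gene table of GRCh38.p14, the source of the coordinates given. That table and the deposited files are both on the GRCh38 assembly.

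Library totals were 2034854 and 5994485 reads in control siRNA replicates 1 and 2, and 6759850 and 2858835 reads in CDH3-AS1 siRNA replicates 1 and 2. A gene with 3 coding-sequence reads stood at 1.63, 0.533, 0.473 and 1.15 CPM, its reads scaled to the library's coding-sequence total, in these libraries in the same order, which is the level below which a gene was not detectable. The depth order differed between the batches, with the control the shallower library in batch 1 and the deeper in batch 2. Intervals on shares of reads are 95% Clopper-Pearson intervals and cover counting error only, since no molecular identifiers were used here. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 41.6 between the controls and 36.7 between the CDH3-AS1 siRNA libraries.

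Coding-sequence counts were summed over the transcripts of a gene name. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 10469. They were tested with edgeR 4.0.16 (TMM scaling, quasi-likelihood test, prior count of 2) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The main model compared the siRNAs with no covariate. The labels give libraries with the same number a shared batch, and deviations of same-numbered libraries from their group means correlated across genes (r = 0.58), so the numbers pair the libraries. The model with the batch as a replicate block is therefore given wherever it changes a call. It has 1 residual degree of freedom per gene against 2 without the block, and draws its variance mainly from the spread over all genes. The biological coefficient of variation was 35.9% without and 20.2% with the block. On simulated counts for the same 10469 genes, the model without the block recovered 0 of 200 changed genes. With the block, 6%, 42%, 72% and 82% of genes changed 1.5-, 2-, 3- and 4-fold were recovered, and 8 of 111 calls (7.21%) were false. Calls that were neither belonged to a simulated list shifted as a whole. The counts were a single draw from the block model's own fit, so they give no false-call rate for the real data.

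Gene lists were compared with all other genes by limma's camera (version 3.58.1, preset correlation of 0.01), with an estimated correlation as an alternative. With an estimated correlation camera tests on the residual degrees of freedom, 2 without the block and 1 with it. A list could then hardly pass, so a call lost there does not show that a shift is absent. Whether the genes of a list moved one way on balance, without regard to other genes, was tested by fry, which rests on the same few degrees of freedom. Of 28 lists, 25 had at least 5 tested genes. The keratinocyte list had 4, the fibroblast list 3 and the list of nuclear and structural noncoding RNAs 1, and these were not tested. The grouping, the main test, the lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took CDH3 and CDH3-AS1, then up to 12 genes per direction past the threshold. Free places went to genes with a mean RPKM of at least 5 and at least 0.5 (log2) in the same direction in each batch, by smallest p, and up to 4 members of each list were added. Since 0 genes passed the main test, all places were filled by the second part. The text names part of these list members. RSAD2, OASL, GBP1, the IFIT genes, XAF1, IFI44L, SLC7A11, COL1A1, COL1A2, the named genes with opposite directions in the batches, the genes with 3′ UTR calls and the muscle genes were chosen after their values were seen. Some genes, and 1 list tested with those in the closing section, are not reported here.

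Alternatives changed the prior count, the filter, the scaling, the variance prior, the transcript that stands for a gene and the test (DESeq2 1.42.0, or limma on log2(RPKM + 1)), or left out each library in turn. Alternatives added after seeing the data counted all reads of a transcript, left out skeletal muscle genes, combined the block with other settings, and exchanged the labels within batch 2. A set of 8 abundant fibroblast and keratinocyte genes, 6 of them with reads in the tables used here, was summed as a check for other skin cells, after a wider set of 12 had been summed first, whose value is given too.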

Results

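Ribosome footprints of Hermes 4B melanocytes were compared between cells that received a control siRNA and cells that received an siRNA against CDH3-AS1. The series asks how this antisense RNA affects expression of CDH3, which encodes the cell adhesion protein P-cadherin. Each siRNA had 2 libraries, 1 per batch, with totals between 2034854 and 6759850 reads. Coding sequence took 90.5% (95% interval 90.5 to 90.6) and 93.9% (93.9 to 93.9) of the reads of control siRNA replicates 1 and 2. In CDH3-AS1 siRNA replicates 1 and 2 it took 93.9% (93.9 to 93.9) and 91.3% (91.3 to 91.3).

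CDH3 had fewer ribosome footprints after CDH3-AS1 siRNA in both batches. Its coding-sequence level was 288 CPM with the control and 180 CPM with CDH3-AS1 siRNA in batch 1, and 321 and 198 CPM in batch 2. The level with CDH3-AS1 siRNA was 62.6% of the control in batch 1 and 61.9% in batch 2. Group means were 304 ± 23.1 CPM (SD, n = 2) for the control and 189 ± 12.9 CPM (SD, n = 2) for CDH3-AS1 siRNA. The log2 fold change of -0.68 (SE 0.32) did not pass edgeR's quasi-likelihood test over all genes (adjusted p = 1.00), nor did it with the replicate block (log2 fold change -0.68, SE 0.25, adjusted p = 0.168). Among the 14 tested genes of the list of cadherins and catenins alone, CDH3 had an adjusted p of 0.0185 with the block, and among the 19 tested genes around it on chromosome 16 an adjusted p of 0.1. Neither list as a whole was called.

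CDH3 lies on chromosome 16 at 68645310 to 68733771 and CDH3-AS1 at 68644248 to 68646201 (GRCh38.p14), so the genes share 892 bases at the lower-coordinate end of CDH3. The level of CDH3-AS1, the siRNA's target, was not analysed here, so its knockdown was not checked. Without known strand, reads in the shared stretch cannot be assigned to either gene. The 5′ UTR held 7.53% of CDH3's 5′ UTR and coding reads in control replicate 1 (95% interval 5.53 to 9.98) and 3.23% in CDH3-AS1 siRNA replicate 1 (2.30 to 4.41). In batch 2 the shares were 4.43% (3.55 to 5.45) and 4.02% (2.50 to 6.07). Fisher's exact test, two-sided, of the reads of the libraries gave p = 1.01e-04 in batch 1 and p = 0.808 in batch 2, and compares those libraries, not the siRNAs. The 5′ UTR share of all reads also fell in batch 1, from 5.98% in the control to 3.81% with CDH3-AS1 siRNA. In batch 2 it rose from 5.08% to 7.09%. The lower CDH3 share in batch 1 is therefore at least partly a difference of the whole libraries.

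**Figure D1:**
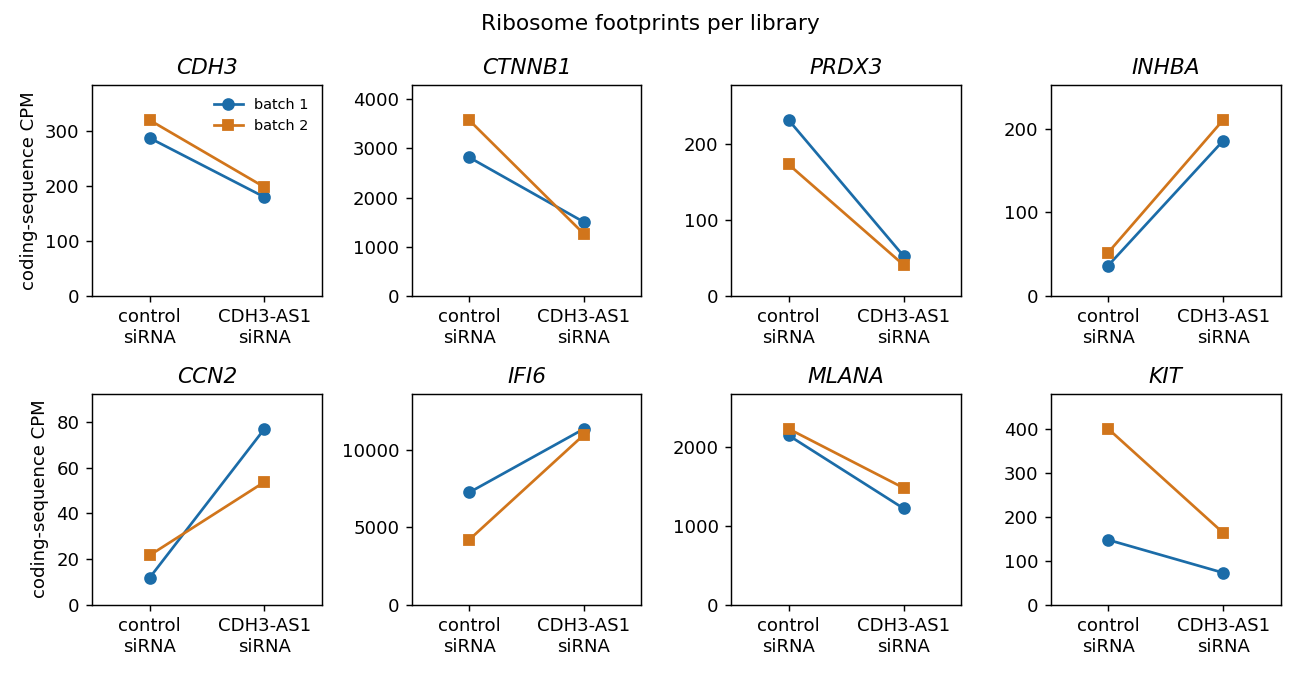
Coding-sequence CPM of 8 genes in each library (vertical axis, from 0), with control and CDH3-AS1 siRNA on the horizontal axis and a line joining the libraries of a batch. CDH3 stands at 288 and 180 CPM in batch 1 and at 321 and 198 CPM in batch 2, and each gene moves the same way in both batches.

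Across all genes, those with the smallest p that moved the same way in both batches included higher INHBA, the activin A subunit, and lower PRDX3, a mitochondrial peroxidase. INHBA had 36.3 and 51.8 CPM in the control libraries and 185 and 210 CPM in the CDH3-AS1 siRNA libraries, a log2 fold change of 2.14 (SE 0.35). PRDX3 had 202 ± 41.2 CPM (SD, n = 2) with the control and 46.6 ± 8.31 CPM with CDH3-AS1 siRNA, a log2 fold change of -2.10 (SE 0.35). CTNNB1, which encodes beta-catenin, the partner of cadherins at cell junctions, had 3197 ± 536 and 1379 ± 171 CPM, a log2 fold change of -1.21 (SE 0.34). Other genes higher in both batches were the semaphorin SEMA3B (1.81), the transcription factors ARID3A (1.79), FOXE1 (1.54) and PLAGL2 (2.11), STARD13 (1.62), PDCD1LG2, the immune checkpoint ligand PD-L2 (1.49), and the kinase PLK2 (1.21). Genes lower in both were NOLC1, a nucleolar protein (-1.80), the zinc finger protein ZBTB41 (-1.98), the lipid phosphatase MTMR4 (-1.57), the proton pump subunit ATP6V1G1 (-1.47), MBLAC2 (-1.67), the adaptor protein SH3KBP1 (-1.38), the reductase PTGR3 (-1.34), the deubiquitinase OTUB1 (-1.52) and the replication helicase subunit MCM6 (-1.19), all as log2 fold changes. C3orf52 was higher and PRAC2 lower in both batches, with no fold given, since C3orf52 had 2 reads in control siRNA replicate 1 and PRAC2 had 3 and 2 reads in the CDH3-AS1 siRNA libraries.

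None of these genes passed the test without the block. By edgeR's quasi-likelihood test 0 of 10469 genes did, with 225 genes at an unadjusted p under 0.05 (110 higher, 115 lower) where 523 would be met by chance. DESeq2 called 2 genes, INHBA and PRDX3, and limma on log2(RPKM + 1) called 0. Without a filter on low counts edgeR called 52 genes, 5 higher and 47 lower. Control siRNA replicate 1 held skeletal muscle transcripts, described below. These can make genes appear lower after CDH3-AS1 siRNA, most of all where that library is the only control. Their part in these calls was not tested. With the replicate block 170 genes passed, 97 higher and 73 lower, among them every gene named in the preceding paragraph. INHBA had an adjusted p of 2.12e-11 with the block, PRDX3 4.27e-11 and CTNNB1 2.07e-06. With the block the count depended on the tool: DESeq2 called 57 genes (38 higher, 19 lower), all of them among the 170, and limma on log2(RPKM + 1) called 0.

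Of the 170 genes, 165 had the same direction in both batches, and 151 differed by at least 0.5 (log2) in each. The block model tests the change combined over the batches, so genes it calls agree in direction largely by selection. Genes with opposite directions included FLNC, PYGM, TPM2 and HNRNPC. FLNC, PYGM and TPM2 are muscle genes with 387, 188 and 205 reads in control siRNA replicate 1. In any other library they had at most 137, 18 and 17. Muscle-expressed genes were also among those called lower with the same direction in both batches. ACTA1 had the smallest adjusted p of all (4.69e-40 by edgeR's quasi-likelihood test with the block), at -7.40 in batch 1 and -0.32 in batch 2. EEF1A2 stood at -4.19 and -0.64, and LDB3 at -3.06 and -1.20. With the labels of batch 2 exchanged, the block model called 0 genes. HNRNPC, an RNA-binding protein, differed in batch 1 alone. Over all tested genes the fold changes of the 2 batches correlated weakly (Pearson's r = 0.18, Spearman's coefficient 0.15, across genes, which are not independent replicates), and 54.3% had the same sign (95% interval 53.3 to 55.3). The batches themselves differed more than the siRNAs, with 538 genes called between batch 2 and batch 1.

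**Figure D2:**
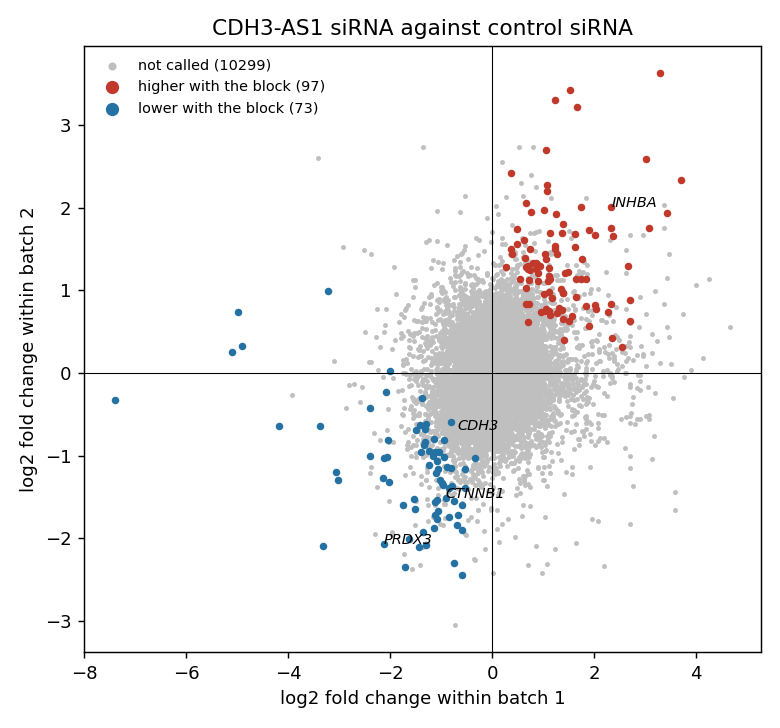
Log2 fold change of CDH3-AS1 siRNA against control siRNA within batch 1 (horizontal axis) and within batch 2 (vertical axis), 1 point per gene. The 97 genes called higher with the replicate block are red, the 73 called lower are blue and the 10469 tested include all others in grey. Of the 170 coloured genes, 165 have the same sign in both batches, largely by selection, against 54.3% of all tested genes.

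Genes of the interferon response, the antiviral programme, were higher after CDH3-AS1 siRNA. The 35 tested members had a median log2 fold change of 0.66, with 0.46 in batch 1 and 0.71 in batch 2; 26 were higher and 0 lower in both batches. IFI6, an interferon-induced membrane protein, had a log2 fold change of 0.97 (SE 0.38), SAMD9 of 0.85 (SE 0.34), SAMD9L of 0.78 (SE 0.32) and IRF7, a transcription factor of the pathway, of 1.36 (SE 0.60). Without the block 0 members passed. With the block 9 were called higher over all genes (IFI6, RSAD2, OASL, GBP1, IFIT2, IFIT3, XAF1, IFIT1 and IFI44L), and 19 adjusted over the list alone, among them SAMD9, SAMD9L and IRF7. IFI6 had an adjusted p of 5.81e-06 with the block and was 0.64 (log2) without control siRNA replicate 2, and the IFIT genes can share reads. limma's camera called the list higher (adjusted p = 2.32e-08), and the call was lost with an estimated correlation (adjusted p = 0.716). It was also lost without CDH3-AS1 siRNA replicate 1 (median 0.05, adjusted p = 0.575) and without control siRNA replicate 2 (median 0.23, adjusted p = 0.877). Without control siRNA replicate 1 the median was 1.30.

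Melanocyte pigmentation genes were lower. The 34 tested members had a median log2 fold change of -0.30, with -0.12 in batch 1 and -0.30 in batch 2; 20 were lower and 6 higher in both batches. RAB38, which serves melanosome traffic, had a log2 fold change of -1.05 (SE 0.37), the melanosome protein MLANA -0.70 (SE 0.32), the endothelin receptor EDNRB -0.89 (SE 0.42) and the stem cell factor receptor KIT -1.22 (SE 0.59). Within batches 1 and 2 KIT was -1.02 and -1.29, and EDNRB -0.94 and -0.82. Leaving out 1 library, which unbalances the batches, moved both. KIT was -0.32 without control siRNA replicate 2, -0.74 without CDH3-AS1 siRNA replicate 1 and -1.91 without CDH3-AS1 siRNA replicate 2. EDNRB was -0.42 without control siRNA replicate 1 and -1.25 without CDH3-AS1 siRNA replicate 1. With the block 6 members were called lower over all genes, and 12 adjusted over the list alone. The camera call (adjusted p = 0.00145) was lost with an estimated correlation (adjusted p = 0.716), without CDH3-AS1 siRNA replicate 1 (adjusted p = 0.0614) and without control siRNA replicate 2 (median near 0, adjusted p = 0.48). Without CDH3-AS1 siRNA replicate 2 the median was -0.49. The culture medium held endothelin-1 and stem cell factor, per the labels' protocols.

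Genes of dedifferentiated or invasive melanoma were higher, with a median of 0.37 over 21 members (0.56 and 0.25 in the batches; camera adjusted p = 1.65e-05, and adjusted p = 0.66 with an estimated correlation). Without CDH3-AS1 siRNA replicate 1 the median was 0.23. With the block 4 were called higher over all genes: INHBA, CCN2 and CCN1, targets of YAP, and NGFR, the neural crest receptor CD271. Adjusted over the list alone, 8 were higher and 1, the receptor kinase AXL, lower (-0.72, SE 0.43), which is also in the TGF-beta and YAP list. AXL was -0.28 without CDH3-AS1 siRNA replicate 2 and -1.39 without CDH3-AS1 siRNA replicate 1. NGFR had a log2 fold change of 1.15 (SE 0.84), with 1.11 in batch 1 and 1.27 in batch 2 (1.19 with the block, SE 0.22). Its controls had 772 CPM in batch 1 and 175 CPM in batch 2, so leaving out 1 library mixes the batch difference with the siRNA. NGFR then turned to -0.17 without CDH3-AS1 siRNA replicate 1. It was 0.46, 1.82 and 2.62 without control siRNA replicate 2, CDH3-AS1 siRNA replicate 2 and control siRNA replicate 1. The TGF-beta and YAP target list was higher too (median 0.36, camera adjusted p = 0.00145, 0.66 as the adjusted p with an estimated correlation), with CCN2 at 1.91 (SE 0.44), CCN1 at 1.08 (SE 0.67) and FJX1 at 0.84 (SE 0.44). CCN1 was 1.84 within batch 1 and 0.81 within batch 2. It was 0.43 without control siRNA replicate 1, 0.51 without CDH3-AS1 siRNA replicate 2 and 2.42 without control siRNA replicate 2. The block called 3 of its 21 members higher over all genes, and 5 higher and 1 (AXL) lower adjusted over the list alone. That call was lost without control siRNA replicate 2 (median 0.08, adjusted p = 0.334) and with at least 50 reads in each library (adjusted p = 0.0795).

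The lists of epithelial-mesenchymal transition and of extracellular matrix were called higher by camera (adjusted p = 0.0313 for each), with estimated-correlation adjusted p of 0.66 and 0.716. In the first, the fibronectin receptor subunit ITGA5 had a log2 fold change of 1.37 (SE 0.34), the actin-binding protein TAGLN 1.91 (SE 0.51), the matrix protein SPARC 0.88 (SE 0.41) and the transcription factor TWIST1 -1.01 (SE 0.56). TWIST1 was -0.48 without CDH3-AS1 siRNA replicate 1, -0.58 without control siRNA replicate 2 and -1.72 without CDH3-AS1 siRNA replicate 2. SPARC was 0.53 without control siRNA replicate 2 and 1.40 without control siRNA replicate 1. The block called 4 of its 20 members higher over all genes, and 5 higher and 1 (TWIST1) lower adjusted over the list alone. Of 23 matrix genes, the basement membrane proteoglycan HSPG2 (1.05, SE 0.38) was called higher and the basement membrane protein NID1 (-1.01, SE 0.34) lower with the block; 6 were higher and 1 lower adjusted over the list alone. HSPG2 was 0.61 without CDH3-AS1 siRNA replicate 2. Left out in turn, control siRNA replicate 1 (adjusted p = 0.104 and 0.0728), control siRNA replicate 2 (0.418 and 0.509) and CDH3-AS1 siRNA replicate 2 (0.147 and 0.503) each ended both calls, and without CDH3-AS1 siRNA replicate 1 the first was lost too (adjusted p = 0.0614). Both calls were lost with no filter on low counts (adjusted p = 0.102 and 0.489). The matrix call was also lost with limma on log2(RPKM + 1) (adjusted p = 0.171) and with the highest transcript in place of the sum (adjusted p = 0.0523). Over all alternatives the median of the first list ran from 0.10 to 0.41 and that of the matrix list from 0.07 to 0.42. Control siRNA replicate 1 also held 496 CPM of 8 abundant fibroblast and keratinocyte genes, mostly COL1A1 (379 CPM) and COL1A2 (111 CPM), against at most 5.04 CPM in the others. Neither collagen passed the filter on low counts, so neither was among the 23 matrix genes. Both entered the fit with no filter, where the matrix call was lost, and their part in that loss was not tested.

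Integrated stress response genes, targets of ATF4, had a median of 0.39 over 34 members (0.32 and 0.36 in the batches), and 25 were higher in both batches. ALDH1L2, a mitochondrial folate enzyme, had a log2 fold change of 1.06 (SE 0.35), the transcription factor ATF3 1.02 (SE 0.36), NUPR1 0.80 (SE 0.39) and the secreted glycoprotein STC2 1.15 (SE 0.66). Without control siRNA replicate 2 NUPR1 was 0.50 and STC2 0.53, without CDH3-AS1 siRNA replicate 1 they were 0.49 and 0.70, and without control siRNA replicate 1 they were 1.21 and 2.05. Over all genes the block called 1 member, the cystine transporter SLC7A11, which was lower (-1.25, SE 0.83); adjusted over the list alone, 7 were higher and 1 lower. Camera called the list higher (adjusted p = 0.00145; adjusted p = 0.716 with an estimated correlation), and the call was lost without control siRNA replicate 2 (median -0.01, adjusted p = 0.989) and without CDH3-AS1 siRNA replicate 1 (median -0.01, adjusted p = 0.777). Nuclear oxidative phosphorylation genes were lower (median -0.21 with the block, camera adjusted p = 0.0107 without it, and adjusted p = 0.66 with an estimated correlation), with 23 of 39 lower in both batches, 0 called by any count, and NDUFB9 at -1.34 (SE 0.57). Leaving out any library but CDH3-AS1 siRNA replicate 2 ended that call, as did limma on log2(RPKM + 1) (median -0.27, adjusted p = 0.074). Over all alternatives the median of the list stayed between -0.27 and -0.14.

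With the block, camera also called the Schwann and neural crest markers higher (12 genes, adjusted p = 0.00426) and the mitochondrially encoded proteins lower (13 genes, adjusted p = 0.00385), with estimated-correlation adjusted p of 0.517 and 0.606. Without the block neither was called with all libraries (adjusted p = 0.144 and 0.679), though the markers passed with no filter on low counts (adjusted p = 0.0483) and with DESeq2 (adjusted p = 0.046). Without control siRNA replicate 1 their medians were 0.65 and -0.95, and without CDH3-AS1 siRNA replicate 2 they were 0.56 and -2.50. The median of the markers was -0.04 without CDH3-AS1 siRNA replicate 1 (adjusted p = 0.73) and 0.08 without control siRNA replicate 2 (adjusted p = 0.872). The mitochondrially encoded proteins went in the opposite direction, higher, without CDH3-AS1 siRNA replicate 1 (0.58) and without control siRNA replicate 2 (1.49). Within batches 1 and 2 their medians were -0.69 and -0.15. Leaving out 1 library sets 1 batch against a mix of both, so a change of direction there can follow the batches and not the siRNA. CDH19, a cadherin of neural crest cells, had a log2 fold change of 1.07 (SE 0.47; 0.59 without control siRNA replicate 1 and 1.91 without control siRNA replicate 2), and the block called CDH19 and NGFR among the markers. Adjusted over the list alone, 4 markers were higher and 1 lower. Over all genes and adjusted over the list alone, 2 mitochondrially encoded genes were called lower. In the list of cadherins and catenins, which did not shift as a whole, the block called CDH19 and the adhesion protein NECTIN2 higher and CTNNB1 lower. The 7 tested WNT and beta-catenin targets had a median of 0.08 with the block (camera adjusted p = 0.804). In the model of all libraries, with or without the block, edgeR's statistics gave no shift for genes around CDH3, cell cycle, DNA replication, p53 targets, the unfolded protein response, heat shock, ribosomal proteins, translation factors, cholesterol synthesis, glycolysis and hypoxia, MAPK output, histones or lysosome. Some alternatives called 3 of these: the unfolded protein response higher with the block and DESeq2, with the block and all reads, and without CDH3-AS1 siRNA replicate 1 (0.24, adjusted p = 0.0392). The cell cycle list was lower without CDH3-AS1 siRNA replicate 2 (-0.39, adjusted p = 0.00638). The histones went both ways, from -0.46 without control siRNA replicate 2 (adjusted p = 1.79e-04) to 0.31 without control siRNA replicate 1 (adjusted p = 0.00957). With an estimated correlation 0 of the 25 lists passed. That test has 2 residual degrees of freedom, or 1 with the block, so a list could hardly pass it. With the labels of batch 2 exchanged and the block, camera with the preset correlation called 2 lists. They were the histones (adjusted p = 5.37e-22) and the cytosolic ribosomal proteins (adjusted p = 1.14e-06). That labelling does not compare the siRNAs, so p-values this small can arise with the preset correlation without an siRNA effect.

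**Figure D3:**
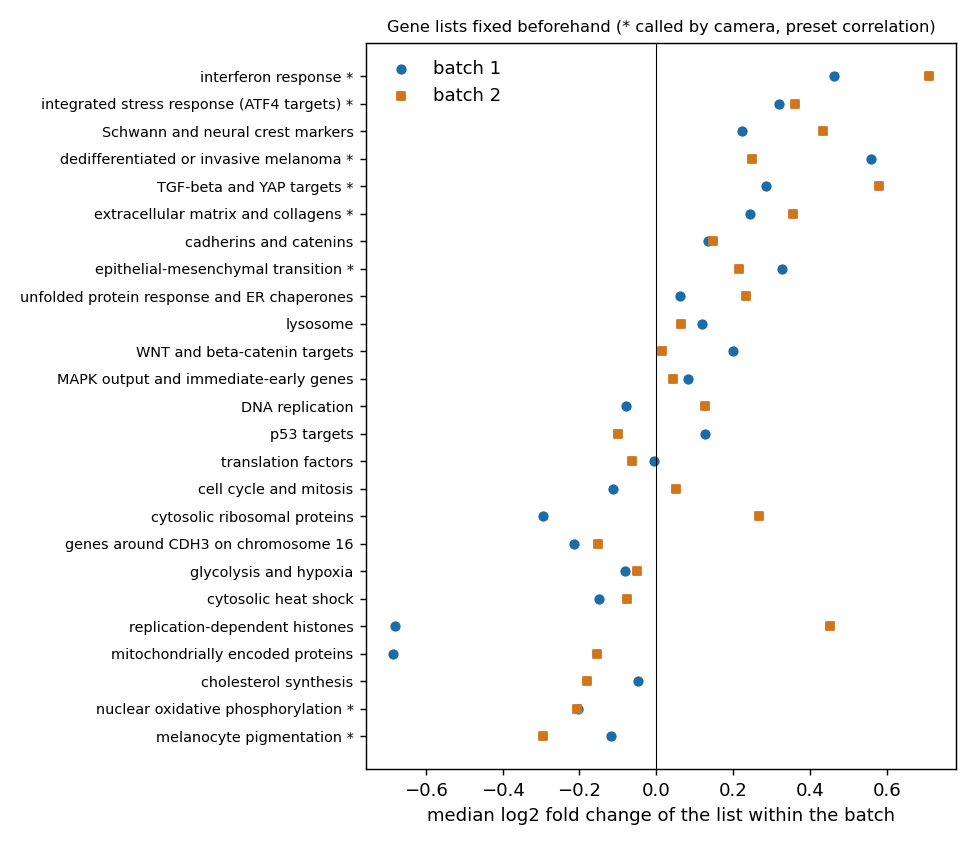
Median log2 fold change of each of the 25 tested gene lists within batch 1 (circles) and batch 2 (squares), sorted by the median over both. A star marks the 8 lists called by camera with a preset correlation. None of them passed with an estimated one, a test with 2 residual degrees of freedom that a list could hardly pass. The interferon response list stands at 0.46 and 0.71, the melanocyte pigmentation list at -0.12 and -0.30.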

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

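The tests of a batch difference, of actin paralogs and of exchanged labels were chosen only after the results were seen, as were the 3′ UTR values. Reads in 3′ UTRs, which the comparisons above leave out, were higher after CDH3-AS1 siRNA than in the controls for 3 genes with the replicate block. The log2 fold changes were 1.99 for IFI6, 2.74 for PPIB and 1.81 for SPARC. IFI6 and SPARC were also higher in the coding sequence, while the coding sequence of PPIB was not called (adjusted p = 0.511 by edgeR's quasi-likelihood test). PPIB had 3 and 16 such reads in the controls and 72 and 90 after CDH3-AS1 siRNA. Lower 3′ UTR reads were called for SLC46A1, TMEM74 and VGF, which had 17002, 300 and 1597 of them in control siRNA replicate 1 against at most 19, 38 and 15 elsewhere. Without the block 0 of 1609 genes were called in the 3′ UTR by edgeR's quasi-likelihood test.

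The interferon response list was called higher after CDH3-AS1 siRNA with a preset correlation, but not with an estimated one (adjusted p = 0.716), nor without CDH3-AS1 siRNA replicate 1 (adjusted p = 0.575) or control siRNA replicate 2 (adjusted p = 0.877). A difference between batches alone is argued against by the within-batch medians, which compare libraries of the same batch. The lower was 0.463 (95% order-statistic interval over the genes of the list, 0.349 to 0.732). Such intervals, here and below, treat genes as independent and do not measure the spread between libraries. Unequal depth is argued against by the design. The control was the shallower library in batch 1 and the deeper in batch 2, and the list was higher in both, at 0.463 and 0.709. After thinning every library to 1827030 coding-sequence reads the lower within-batch median was 0.519. Random thinning keeps the expected proportions of reads, so it could hardly have removed the shift and decides little. An effect of the siRNA on CDH3-AS1, whose knockdown was not checked here, and a response to the transfected RNA itself cannot be told apart, because there was 1 targeting siRNA group.

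Pigmentation genes were called lower and genes of invasive melanoma higher with a preset correlation, but not with an estimated one (adjusted p = 0.716 and 0.66). Cells of another skin type that express them are argued against by 8 abundant fibroblast and keratinocyte genes, which reached at most 5.04 CPM together in the CDH3-AS1 siRNA libraries (37.9 CPM over the wider set of 12). Some other listed markers had reads in every library. FAP had 92.8 CPM with the control and 95.1 with CDH3-AS1 siRNA in batch 1, and 341 and 238 in batch 2. PERP had 275 and 307, then 194 and 166 CPM. LAMB3 was higher in both batches, with 14.7 and 16.5, then 9.06 and 14.6 CPM. The test of unequal depth could not decide, since batch 1 showed no clear shift with or without thinning. Its pigmentation median was -0.12 (interval -0.54 to 0.14) as deposited and -0.145 (-0.46 to 0.10) after thinning, and both intervals cover 0. In batch 2 it was -0.30 as deposited and -0.34 (-0.57 to -0.13) after thinning, so thinning weakened neither pigmentation median. The invasive list had thinned medians of 0.30 (-0.09 to 1.15) and 0.38 (0.01 to 1.04). An effect of CDH3-AS1 on the state of the cells may also underlie the pattern and was not tested separately.

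Control siRNA replicate 1 held skeletal muscle transcripts, with 1858 reads of ACTA1 against 65 in the other 3 libraries together. RNA of another sample in that library is a candidate explanation. Of 29 muscle genes outside the actin family not looked at before, 27 had a log2 excess over 1 (all but TRIM63 and ALDOA), and the median was 4.09 (interval 3.39 to 5.19), with TTN at 3285 reads against 9. The same median argues against reads shared between actin paralogs as the whole cause. Muscle genes took 0.575% of its coding reads, and no biological explanation was tested.

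The 170 genes called with the replicate block compare with 0 when the labels of batch 2 are exchanged. Only 2 labellings exist within the batches, of which 1, the real one, gave as many genes, so the design is too small for a share under 0.05.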

How the results depend on the processing

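Alternatives that count all reads, leave out muscle genes, combine the replicate block with another setting or exchange labels were chosen after seeing the data. CDH3 kept its direction and stayed short of the threshold in all 24 alternatives, with log2 fold changes from -0.76 to -0.59 and adjusted p from 0.133 to 1.00. The count of genes over all tested was 0 and became 52 with no filter on low counts, 170 with the replicate block and 2 with the DESeq2 Wald test, and ran from 0 to 11 with each library left out in turn. A lone remaining library is then assumed to vary like the other group, and the cause was not tested. Under the block, the 170 genes became 57 with DESeq2 and 0 with limma on log2(RPKM + 1); other block settings gave 127 to 191. Leaving out a library under the block leaves no residual degrees of freedom and could not be fitted.

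The 8 list calls became 10 with the block, 0 with an estimated correlation, and 0 with the block and an estimated correlation. With the block and labels exchanged within batch 2 there were 2 calls, the histones and the cytosolic ribosomal proteins, neither among the 8. The estimated correlation leaves camera 2 residual degrees of freedom, or 1 with the block, so a list could hardly pass. fry, which tests a list against no change and not against other genes, called 0 lists (smallest adjusted p = 0.14). With each library left out in turn, 3 to 10 lists were called. The integrated stress response median was -0.0107 without CDH3-AS1 siRNA replicate 1 and reached 0.76, that of the mitochondrially encoded proteins ran from -2.50 to 1.49, and NGFR from -0.17 to 2.62. By the direction of each test, over all single lists and genes followed, 1014 values kept direction and side of the threshold, 63 were newly past it, 32 no longer past it and 4 reversed. Since the main fit called 0 genes, a gene that kept its side only stayed uncalled. Part of the genes had been chosen for the same direction in both batches, so these numbers do not measure stability. The medians of 2 more lists changed sign while the test did not: the Schwann and neural crest markers without CDH3-AS1 siRNA replicate 1 (-0.04) and the integrated stress response without control siRNA replicate 2 (-0.01). Leaving out 1 library unbalances the batches, which differ in 538 genes, so values with a library left out mix the batch difference with the siRNA. Within the batches NGFR was 1.11 and 1.27, and the median of the mitochondrially encoded proteins -0.69 and -0.15. The correlation of the batches' fold changes was 0.18 and was 0.21 and 0.24 with a mean RPKM of at least 10 and 50, and the cause was not tested. It was -0.42 when libraries were paired across batches.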

Other observations

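The beta-catenin test and the ribosome biogenesis median with all genes kept were chosen only after the results were seen. The gene lists below were written after single members had been seen, and tested without them for a shift of the whole pathway, and camera called none of those given here. WARS1, the tryptophanyl-tRNA synthetase, was itself not called (log2 fold change 0.56 with the block, adjusted p = 0.153 by edgeR's quasi-likelihood test). Aminoacyl-tRNA synthetases other than WARS1 had a median of 0.0172 (interval -0.14 to 0.32), with 6 of 16 genes also in the integrated stress response list. V-ATPase subunits other than ATP6V1A and ATP6V1G1 had a median of -0.082 (-0.35 to 0.16), with 4 of 14 in a list tested above. Ribosome biogenesis genes other than NOLC1, DKC1, LSG1 and POLR1E had a median of -0.000912 (-0.20 to 0.12). With those 4 genes, all called lower with the block, the median was -0.02 (-0.23 to 0.08), which argues against a large drop of the whole list and leaves a smaller one open. For lower CTNNB1, the median of 7 beta-catenin targets was 0.0788 (-0.49 to 0.61), too wide an interval to tell whether they moved with it.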
